A study of Mus musculus with 16 samples.

How the data were processed

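Total RNA of MALT1-deficient CD4-positive T cells from 4 C57BL/6 mice was hybridised to 1-colour Illumina bead arrays, 16 in all. Per the labels' protocols, the cells of each mouse were given MALT1 isoform A, MALT1 isoform B or a mock vector by retrovirus, stimulated through CD3 and CD28 for 2.5 h or, for isoform A alone, also left unstimulated. RNA was extracted with Trizol and cleaned on a column, and biotin-labelled cRNA was made with an Ambion kit, per the labels' protocols. Each of the 4 groups held 4 arrays, 1 per mouse, and the replicate number of a label stood for a mouse.

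The deposited unnormalized intensity values were mean bead signals per probe on a linear scale with no background subtracted, as the values show, and they came from GenomeStudio 2011.1, per the submitters' processing notes. A detection p-value per probe and array was deposited beside each signal, per the file headers, and its steps implied 798 negative control beads. The deposited value table of the series held the authors' background-subtracted intensity values of the same arrays. Its values went down to -20.47 and its upper quartiles were 101.9 to 102.9, which a log scale would not give, so it was taken as linear. Each of its columns had the same rank order of probes as that array's own unnormalized signal, so no centring of genes was seen, but the method of normalization is not stated. Its column medians for mice 1 to 4 were 8.077, 8.109, 8.088 and 8.084 in isoform A unstimulated cells, and 8.09, 8.088, 8.08 and 8.078 in isoform A stimulated cells. They were 8.08, 8.078, 8.065 and 8.088 in isoform B stimulated cells and 8.098, 8.079, 8.108 and 8.103 in mock stimulated cells. That table was used as an alternative.

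From the unnormalized intensities, background was corrected with limma's normexp model on the detection p-values, followed by quantile normalization and log2 after an offset of 16 (limma 3.58.1, statmod 1.5.0, R 4.3.3). Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were unnamed here. The gene identifiers of 23962 probes matched a mouse gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. A probe was kept when its detection p was under 0.05 on at least 4 of the 16 arrays, which left 12344 probes, of which 740 were unnamed. The probe with the highest mean log2 intensity stood for each gene, so that 8480 genes were tested, and 2201 of them had more than 1 detected probe. Symbols are those of the array's annotation and can be old.

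Comparisons were made with limma's moderated test on a model of 4 group means over all 16 arrays, with 12 residual degrees of freedom, 2-sided, and Benjamini-Hochberg adjustment over the genes tested per comparison at a threshold of 0.05. All adjusted p-values are from limma. Errors written after ± are standard errors (SE) of this fit with n = 4 mice per group unless SD is named. The fit has 1 spread per gene for all 4 groups. Where 1 group varied more than the others, the SE and p-value do not show it. Same-numbered arrays came from the same animal, so the numbers paired the arrays. After removal of group means, arrays of the same mouse correlated across genes with a mean r of 0.289 (0.131 to 0.417 over 24 pairs), and arrays of other mice with a mean r of -0.0962 (72 pairs). The model without the mouse was written as the main design before the data were examined, as were the gene lists, the rule for named genes and the alternatives unless stated otherwise, and the model with the mouse as a block is an alternative whose value stands beside a result where it changes a call or moves a count by over 1.5 times. On simulated data for isoform A against mock (8480 genes), the main model recovered 40.3% of genes changed by 0.5 on the log2 scale, 91% of those changed by 1 and 100% of those changed by 2, with 3.14% false calls among its calls, and the model with the mouse as a block recovered 55.2%, 95.5% and 100% with 6.18% false calls. The simulation used 1 draw per model, normal noise independent between genes, equal spread in all groups and an assumed mouse effect. The real arrays of a mouse correlated across genes, so these shares need not hold for them.

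Fixed were 24 gene lists: NF-kB pathway and feedback targets, immediate early and AP-1 family genes, NFAT-calcineurin responsive genes, T cell cytokines and chemokines, activation and costimulatory receptors, MALT1 protease substrates, Regnase-1 and Roquin target mRNAs, CBM complex and IKK signalling, T cell receptor proximal signalling, MAPK feedback regulators, cytokine signalling and STAT targets, quiescence and homing genes, T helper lineage transcription factors, apoptosis regulators, glycolysis and nutrient transport, ribosome biogenesis, mitosis and DNA replication, interferon-stimulated genes, heat shock and unfolded protein response, housekeeping genes, and markers of B cells, of macrophages and dendritic cells, of CD8 and cytotoxic lymphocytes, and of erythroid cells and granulocytes. Some lists share members, so their results are not independent. Tnfaip3, Cyld and Relb are on both the NF-kB and the MALT1 substrate list. Rel, Nfkbid and Nfkbiz are on both the NF-kB list and that of Regnase-1 and Roquin targets. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way and compares with no other genes, were alternatives. Named were, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with the same sign in all 4 mice, up to 4 members with the largest change from each list among those past the threshold (or the 1 member with the smallest p, as a value), and Malt1, Il2, Nfkbia and Tnfaip3. Other members of a list are named as chosen after their values were seen. Il2 is not analysed here.

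A gene not above background (detection p of 0.05 or more) on every array of 1 group has only a bound there: its fold is given as "at least", the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own. A gene above background on only some arrays of a group has no such bound, and its fold is less certain. Isoform A and isoform B were each set against the same mock arrays, so their shared variation was simulated with unchanged groups. Other alternatives were the background correction, the normalization, the detection filter, the probe per gene, the variance model, the samples in the fit, a threshold on the fold, the mouse as a fixed or random block, and leaving out each mouse and each array. A slide is not given for these arrays, so no slide block was fitted.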

Results

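Gene expression was measured on 16 bead arrays of RNA from MALT1-deficient CD4-positive T cells of 4 mice. MALT1 is the protease and scaffold that links the T cell receptor to NF-kB, and the study's title concerns its alternative splicing on receptor stimulation. The cells of each mouse were reconstituted with MALT1 isoform A, isoform B or mock vector and stimulated through CD3 and CD28, the T cell receptor complex and its costimulatory receptor, for 2.5 h. A further portion with isoform A stayed unstimulated. Median raw intensity was between 121.8 and 138.8 on the 16 arrays. Between 10247 and 11012 of 25697 probes were detected on the 12 stimulated arrays and between 11239 and 12085 on the 4 unstimulated arrays. Arrays of a group correlated with an r of 0.9902 to 0.9962 over detected probes, and the first principal component, which held 83.4% of the variance, separated stimulated from unstimulated arrays. The number of arrays limits the precision. The arrays of mice 1 and 2 had a highest raw intensity of 34329 to 38404 and those of mice 3 and 4 of 41735 to 43710, a split that crosses all 4 groups.

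Malt1 itself was read by 1 probe, which was detected on 4 of 16 arrays at raw intensities of 120.1 to 140.4. Its level differed by 0.01 ± 0.13 on the log2 scale between stimulated and unstimulated isoform A cells (adjusted p = 0.939) and by -0.13 ± 0.13 between isoform A and mock (adjusted p = 0.658). It was not above background on any isoform B array, so no difference from isoform B is given. Whether this probe lies in the part held by the transgenes is not known here, so it checks nothing about the labels.

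The first comparison asked which genes respond to 2.5 h of stimulation in cells with isoform A. Cytokine and early response genes rose most: Il3 rose at least 1310-fold (adjusted p = 7e-21). Csf2, which encodes the cytokine GM-CSF, rose 192-fold (log2 7.59 ± 0.17), the transcription factor gene Egr2 177-fold (log2 7.47 ± 0.15) and the chemokine gene Ccl1 129-fold (log2 7.02 ± 0.25). The quiescence factor Klf2 fell by 6.17 ± 0.15 on the log2 scale (72.0-fold), the cell cycle regulator E2f2 by 5.67 ± 0.15 (51.0-fold) and the thioredoxin inhibitor Txnip by 4.89 ± 0.16 (29.7-fold). Of 8480 genes, 5634 passed the threshold (66.4%), 2512 higher and 3122 lower, and 2533 of them changed by at least 1 on the log2 scale. The other largest rises were those of Sphk1 (at least 90.7-fold), 1810009J06Rik (121-fold), Tnfsf14 (114-fold), Bdh2 (67.9-fold), Rgs16 (66.9-fold) and Ccl3 (66.6-fold). Bdh2, and Cd83 named below, were each above background on 1 of 4 unstimulated arrays, so their folds are uncertain. The other largest falls were those of Fam78a (44.6-fold), Ypel3 (28.3-fold), Tspan32 (23.8-fold), Tbc1d10c (23.8-fold), Tbxa2r (at least 14.2-fold), Pxylp1 (21.3-fold) and AI467606 (21.1-fold). With each array scaled to the same median in place of quantile normalization, the median of all genes shifted by -0.223 and 1651 genes were higher and 3652 lower, so changes near 0 are relative to that choice. No list past the test turned its direction under that scaling, with no background correction or with the authors' table.

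Lists of signalling and effector genes moved up together. Of 27 measured T cell cytokines and chemokines, 25 rose and 1 fell (camera, adjusted p = 1.15e-10), among them Tnf (log2 5.46 ± 0.13) and the interferon gamma gene Ifng (57.1-fold). Of 22 NF-kB pathway and feedback genes, 18 rose and 4 fell (adjusted p = 1.2e-06). Rel was 32.3-fold, Cd83 23.4-fold, Bcl2a1d 14.9-fold and, among inhibitor genes, Nfkbid 11.9-fold, Tnfaip3 11.6-fold and Nfkbia 4.83-fold higher. Cyld, Birc2, Bcl3 and Tnip1 fell by 1.53, 1.45, 1.20 and 0.87 (these 4 were chosen after their values were seen). Of 21 immediate early and AP-1 genes, 16 rose and 1 fell (adjusted p = 2.97e-07), including Atf3 (30.2-fold), Nr4a2 (at least 29.3-fold) and Nr4a3 (at least 27.5-fold). Of 24 activation and costimulatory receptors, 17 rose and 4 fell (adjusted p = 0.000129), with Crtam 34.5-fold, Cd40lg 27.4-fold, Slamf1 14.8-fold and Havcr2 10.7-fold higher. Of 13 mRNAs that Regnase-1 and Roquin target, 10 rose and 2 fell (adjusted p = 0.000104), among them Pim3 (12.2-fold). Of 13 MAPK feedback regulators, 9 rose and 2 fell (adjusted p = 0.000289), with Gadd45b 36.2-fold, Dusp4 28.7-fold and Dusp2 12.1-fold higher. Among 19 ribosome biogenesis genes 18 rose and 0 fell (adjusted p = 8.87e-10), with Rrp9 8.30-fold, Pes1 5.67-fold, Nop2 5.43-fold and Rrs1 4.06-fold higher. These 7 calls held with an estimated correlation (adjusted p of 0.0188 to 0.0384). Of 20 glycolysis and nutrient transport genes 14 rose and 0 fell (adjusted p = 0.00114), among them Slc1a5 (4.86-fold), Hk2 (4.28-fold), Slc7a5 (3.21-fold) and Slc3a2 (3.14-fold), but the adjusted p = 0.0677 with an estimated correlation. Of 18 heat shock and unfolded protein response genes 11 rose and 1 fell (adjusted p = 0.00679, and adjusted p = 0.0842 with an estimated correlation), with Chac1 21.4-fold, Hspa5 4.82-fold, Asns 4.24-fold and Hsph1 3.87-fold higher. Adjusted over the list alone, the counts were the same in each of these lists except that 2 immediate early genes fell.

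Cell cycle and quiescence genes fell. Of 21 mitosis and DNA replication genes 0 rose and 20 fell (adjusted p = 3.35e-08, and 0.0332 with an estimated correlation), with Cdc6 6.67-fold, Plk1 6.53-fold, Ccne2 6.00-fold and Birc5 5.22-fold lower. Of 19 quiescence, homing and memory genes 3 rose and 16 fell (adjusted p = 0.000224, but adjusted p = 0.0808 with an estimated correlation), among them Klf2, Txnip, Ypel3 and the PI3K inhibitor gene Pik3ip1 (at least 7.57-fold). The counts adjusted over the list alone were the same in both.

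Other lists held members that moved both ways and did not pass as lists. Of 24 interferon-stimulated genes 4 rose and 14 fell (adjusted p = 0.249), with Ifit3 11.3-fold, Ifit2 10.2-fold, Igtp 4.24-fold and Ddx58 3.70-fold lower. Of 15 cytokine signalling and STAT genes 6 rose and 7 fell (adjusted p = 0.711, median -0.0241 and mean 0.224, which differ in sign), with Jak2 10.2-fold and Il6st 6.89-fold higher and the feedback inhibitor gene Socs3 8.62-fold lower. T helper lineage factors numbered 7 higher and 3 lower of 14 (adjusted p = 0.0897), with Bcl6 (log2 4.46 ± 0.17), Tbx21 (log2 3.46 ± 0.10), Irf8 (6.83-fold) and Zbtb32 (6.51-fold) higher. NFAT-calcineurin genes numbered 6 higher and 3 lower of 11 (adjusted p = 0.18), with Tnfrsf9 6.86-fold and Spry1 at least 5.75-fold higher and Rcan3 7.40-fold lower. MALT1 substrates numbered 6 higher and 3 lower of 11 (adjusted p = 0.0624), with Relb 6.71-fold, Bcl10 3.08-fold and Zc3h12a 2.93-fold higher. CBM complex and IKK genes numbered 4 higher and 8 lower of 16 (adjusted p = 0.711), with Prkcq 3.22-fold, Casp8 2.76-fold and Ikbkg 2.59-fold lower. T cell receptor proximal genes numbered 7 higher and 6 lower of 18 (adjusted p = 0.385), with Sla 6.32-fold, Lcp2 5.55-fold and Ptpn22 3.40-fold higher and Ptpn6 4.83-fold lower. Apoptosis regulators numbered 5 higher and 5 lower of 14 (adjusted p = 0.897, median 0.0594 and mean -0.0854, which differ in sign), with Fasl 12.8-fold higher and Bbc3 7.58-fold and Bcl2 3.37-fold lower. Of 11 housekeeping genes 2 rose and 3 fell (adjusted p = 0.711), with Tubb5 4.13-fold and Actb 1.77-fold lower, while the calls of Rplp0 (log2 0.42 ± 0.08) and Hprt (log2 -0.29 ± 0.10) were lost with median scaling and another probe of Hprt had a difference of 0.251. Adjusted over the list alone, the counts of these 9 lists were the same except that 8 T cell receptor proximal genes rose.

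Markers of other cells were measured beside these changes. Of 7 B cell markers Cd74 and H2-Ab1 rose by log2 1.42 ± 0.37 (adjusted p = 0.00235) and 0.83 ± 0.33 (adjusted p = 0.037) and Cd79b fell at least 1.17-fold (list adjusted p = 0.711), and the call of H2-Ab1 was lost with the mouse as a block (adjusted p = 0.0532) and with median scaling. Adjusted over the list alone, 1 B cell marker rose and 1 fell. Of 9 CD8 and cytotoxic markers Prf1 rose 2.85-fold and Ctsw and Klrd1 fell 1.61-fold and 1.52-fold (list adjusted p = 0.831), with the same counts adjusted over the list alone. Of 4 macrophage and dendritic cell markers 0 passed, also adjusted over the list alone, and Ctss differed by 0.25 ± 0.15 (adjusted p = 0.161). Of 4 erythroid and granulocyte markers Car2 rose at least 1.79-fold, also adjusted over the list alone, and lists of 4 were not tested as lists.

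The second comparison asked what isoform A adds to stimulated cells beside mock. The chemokine gene Ccl9 was 11.8-fold higher with isoform A (log2 3.56 ± 0.29, n = 4, adjusted p = 4.5e-06), the TNF family ligand Cd70 5.34-fold (log2 2.42 ± 0.52, adjusted p = 0.0124). Il4i1 was 4.89-fold higher (log2 2.29 ± 0.35, adjusted p = 0.00114) and Il23a, a subunit of interleukin 23, 4.26-fold (log2 2.09 ± 0.22, adjusted p = 4.81e-05). The alpha globin gene Hba-a1 was 4.98-fold lower (log2 -2.32 ± 0.51, adjusted p = 0.0149) and the interferon-induced gene Rsad2 4.00-fold lower (log2 -2.00 ± 0.45, adjusted p = 0.0168). The SDs of Hba-a1 and Rsad2 were 1.505 and 1.278 over the mock arrays, and 0.3663 and 0.4368 over the isoform A arrays. In all, 412 genes passed, 221 higher and 191 lower. Of these, 46 differed by at least 1 on the log2 scale and 399 had the same sign in all 4 mice. With the mouse as a block 745 genes passed, 375 higher and 370 lower, and 411 of the 412 were among them. Further large rises were those of the collagenase gene Mmp13 (3.86-fold), Mzb1 (3.84-fold), Timp1 (3.73-fold), Idi2 (3.44-fold), Il10 (3.13-fold) and Cd74 (3.13-fold). Further large falls were those of Oasl2 (3.12-fold), Ramp3 (2.92-fold), Hspa1a (2.61-fold), Gpr146 (2.56-fold), Rab19 (2.41-fold), Atp6v0a1 (2.40-fold), Lmo2 (2.33-fold) and Slc7a3 (2.28-fold). Mzb1 and Timp1 were above background on 1 and 2 of 4 mock arrays. Atp6v0a1 was above background on 1 of 4 isoform A arrays, and Rab19, Gpr146 and Hspa1a on 2, so these folds are uncertain.

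**Figure D1:**
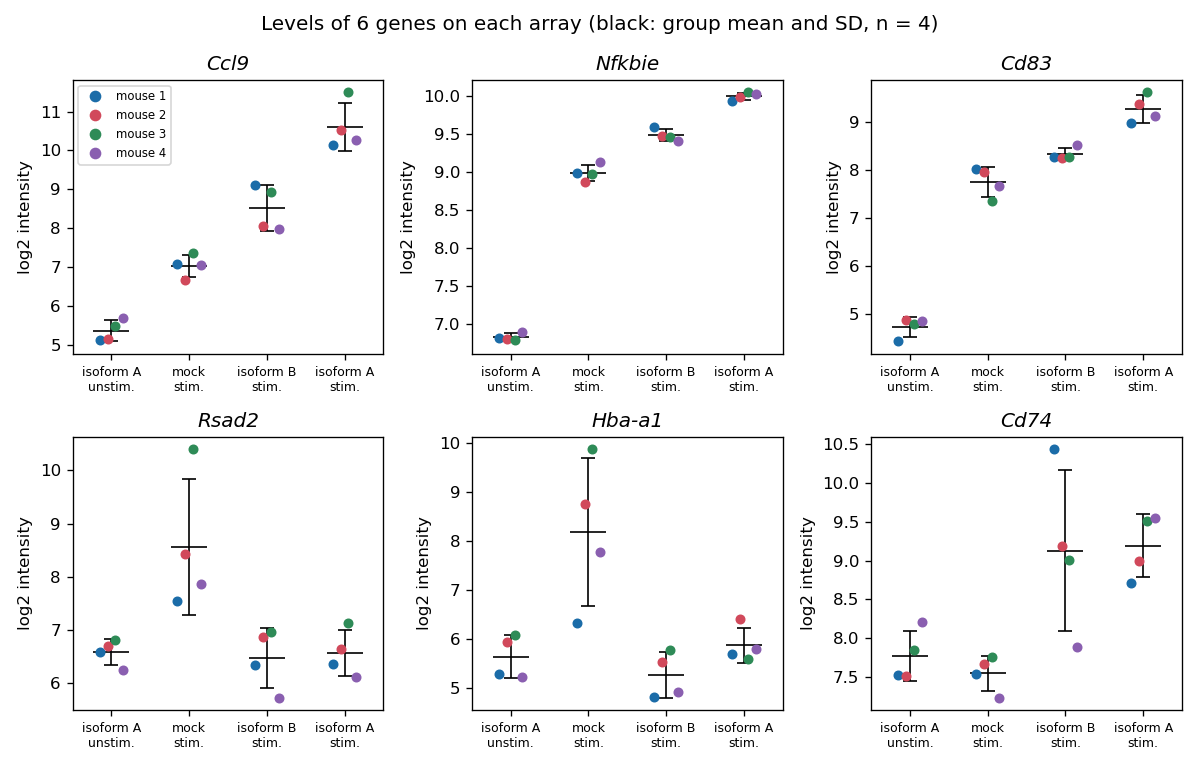
Log2 intensity (y axis) of 6 genes on each of the 16 arrays, by group (x axis), with points coloured by mouse and black lines for the group mean and SD (n = 4). Ccl9, Nfkbie and Cd83 were higher with isoform A than with mock in all 4 mice, and Rsad2 and Hba-a1 were highest on the mock array of mouse 3.

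NF-kB genes were the group with the lowest p beside mock. Of 22 measured members 11 were higher with isoform A and 0 lower (camera, adjusted p = 8.32e-15, and adjusted p = 0.0144 with an estimated correlation), and 13 were higher adjusted over the list alone. Cd83 was 2.88-fold higher (log2 1.52 ± 0.16, adjusted p = 4.28e-05) and the inhibitor gene Nfkbie 2.01-fold (log2 1.01 ± 0.08, adjusted p = 3.59e-06). The adhesion molecule gene Icam1 was 1.70-fold higher (log2 0.76 ± 0.15, adjusted p = 0.00634) and Ier3 1.64-fold (log2 0.71 ± 0.14, adjusted p = 0.00588). Tnfaip3 differed by 0.40 ± 0.12 (adjusted p = 0.0711) and Nfkbia by 0.26 ± 0.12 (adjusted p = 0.259).

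Of 27 cytokines and chemokines 7 were higher and 1 lower (adjusted p = 7.35e-07, but adjusted p = 0.158 with an estimated correlation). Of these, 11 were higher and 1 lower adjusted over the list alone. Il17f was 2.86-fold higher, Ccl5 2.27-fold and Tnf 2.03-fold, beside Ccl9 and the anti-inflammatory cytokine gene Il10. Of 11 MALT1 substrates 3 were higher and 0 lower (adjusted p = 0.000645, but adjusted p = 0.084 with an estimated correlation). Zc3h12a, Relb and Map3k14 were at log2 0.56 ± 0.16, 0.55 ± 0.10 and 0.44 ± 0.10, and 4 members were higher adjusted over the list alone. Of 13 Regnase-1 and Roquin targets Tnf, Zc3h12a and Irf4 (log2 0.55 ± 0.15) were higher (adjusted p = 0.00858, but adjusted p = 0.194 with an estimated correlation), and 4 were higher adjusted over the list alone. Of 15 cytokine signalling and STAT genes 3 were higher, Stat5a by 2.73-fold, the kinase gene Pim1 by 1.95-fold and Il6st by 1.48-fold (5 higher and 1 lower adjusted over the list alone). As a list they passed narrowly (adjusted p = 0.05 after rounding), and not with the mouse as a block (adjusted p = 0.0544) or with an estimated correlation (adjusted p = 0.192). Among 24 activation receptors Lag3 (1.83-fold), Cd40lg (1.69-fold) and Cd44 (1.36-fold) were higher and Cd28 (1.31-fold) lower (list adjusted p = 0.151, with 5 higher and 1 lower adjusted over the list alone). Among 14 T helper factors Zbtb32 (1.56-fold), Rora (1.55-fold) and Irf4 were higher and Bcl6 (1.63-fold) lower (list adjusted p = 0.667, same counts adjusted over the list alone). The survival genes Bcl2l1 and Bcl2 moved apart among 14 apoptosis regulators, at log2 0.68 ± 0.17 and -0.35 ± 0.09 (list adjusted p = 0.805, same counts adjusted over the list alone). Of 11 NFAT-calcineurin genes the calcineurin regulator Rcan1 was 2.00-fold higher (list adjusted p = 0.708, median 0.00335 and mean -0.0377, which differ in sign, with 1 higher and 1 lower adjusted over the list alone).

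Interferon-stimulated genes were lower as a list with isoform A than with mock (adjusted p = 0.00467, but adjusted p = 0.478 with an estimated correlation). The list call was lost without the mock array of mouse 3 (adjusted p = 0.12, mean -0.236 instead of -0.505), where the mean difference was -1.15 against -0.185, -0.478 and -0.205 in mice 1, 2 and 4. Of 24 members 2 were lower, Rsad2 and Oasl2, and 2 higher, Gbp2 (log2 0.46 ± 0.12) and Gbp3 (log2 0.56 ± 0.14). Adjusted over the list alone 8 were lower and 2 higher. Of 18 heat shock and unfolded protein response genes Hspa1a, Ddit3 (2.00-fold) and Ddit4 (1.63-fold) were lower (list adjusted p = 0.0793, 4 lower adjusted over the list alone). Among 20 glycolysis genes Slc2a3 (1.88-fold) and Hif1a (1.73-fold) were lower (list adjusted p = 0.074, with 2 higher and 5 lower adjusted over the list alone). Among 19 quiescence genes Tsc22d3 (1.76-fold) and Satb1 (1.66-fold) were lower (list adjusted p = 0.074, same counts adjusted over the list alone). Of 21 immediate early genes Zfp36 (1.59-fold), Fos (1.48-fold) and Jund (1.42-fold) were lower (list adjusted p = 0.802, median 0.056 and mean -0.0513, which differ in sign, with 4 lower adjusted over the list alone). Of 18 T cell receptor proximal genes Ptprc (1.67-fold) and Ptpn6 (1.60-fold) were lower (list adjusted p = 0.144, same counts adjusted over the list alone), although another probe of Ptprc had a difference of 0.171. No member passed among 16 CBM complex genes (adjusted p = 0.454, Rnf31 0.41 ± 0.12 with adjusted p = 0.0535, or 0.0202 with the mouse as a block, and 1 higher and 2 lower adjusted over the list alone). No member passed, also adjusted over the list alone, among 13 MAPK feedback regulators (adjusted p = 0.708, Gadd45g -0.24 ± 0.09) and 19 ribosome biogenesis genes (adjusted p = 0.454, Polr1c 0.29 ± 0.10). The same held for 21 mitosis genes (adjusted p = 0.708, median 0.0172 and mean -0.0561, which differ in sign, Ccne2 -0.48 ± 0.17) and 11 housekeeping genes (adjusted p = 0.0965, Actb -0.43 ± 0.14).

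Markers of other cell types moved with isoform A beside these groups. Of 7 B cell markers Cd74 (log2 1.65 ± 0.37, adjusted p = 0.0152) and H2-Ab1 (log2 1.52 ± 0.33, adjusted p = 0.0144), both of the MHC class II pathway, were higher, also adjusted over the list alone. The list passed (adjusted p = 0.0193) but not with the authors' table (adjusted p = 0.0854) or with an estimated correlation (adjusted p = 0.194). Of 4 erythroid and granulocyte markers Hba-a1 and Car2 (1.91-fold) were lower, also adjusted over the list alone. None of 9 CD8 and cytotoxic markers (adjusted p = 0.805, Eomes -0.49 ± 0.22, median 0.0396 and mean -0.011, which differ in sign) or of 4 macrophage and dendritic cell markers (Cst3 0.25 ± 0.15) passed, also adjusted over the list alone. The count of 412 genes fell to 136 with median scaling and 161 with the isoform A and mock arrays alone, and 41 genes passed in mice 1 and 2 and 490 in mice 3 and 4. Leaving out the mouse 3 array of isoform A left 200 genes and leaving out the mouse 4 array of mock left 262.

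**Figure D2:**
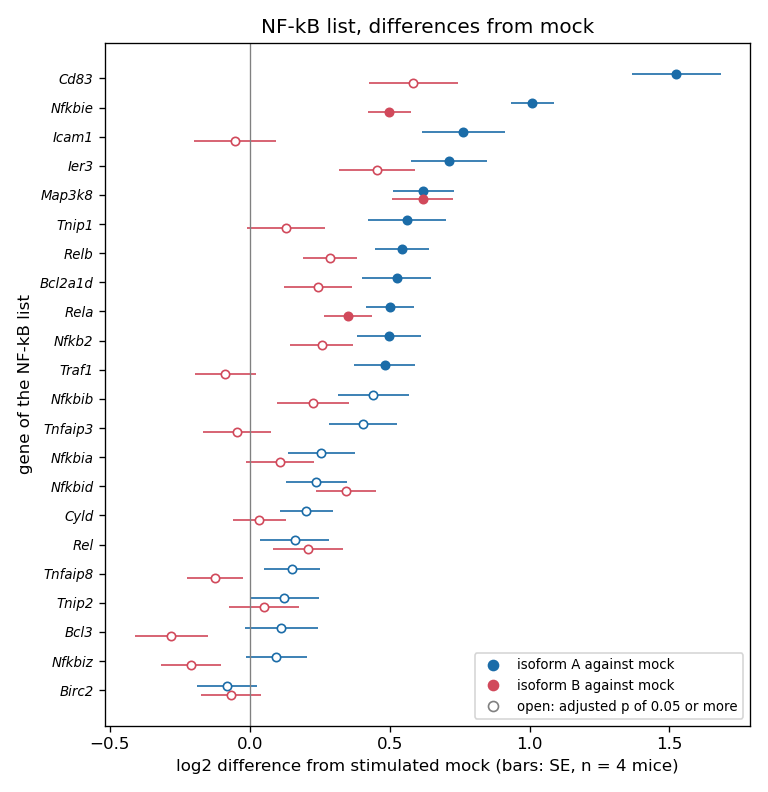
Log2 differences from stimulated mock (x axis, bars SE, n = 4) of the 22 measured NF-kB list genes (y axis) for isoform A and isoform B, with open points where the adjusted p was 0.05 or more. With isoform A 11 genes passed and with isoform B 3.

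The third comparison put isoform B beside the same mock cells. Mzb1, a gene of the endoplasmic reticulum in B lineage cells, was 6.89-fold higher with isoform B (log2 2.78 ± 0.52, n = 4, adjusted p = 0.00864), the cytokine gene Il17f 3.24-fold (log2 1.69 ± 0.29, adjusted p = 0.00492) and Ccl9 2.79-fold (log2 1.48 ± 0.29, adjusted p = 0.0129). The SD of Mzb1 was 1.621 over the isoform B arrays and 0.3501 over the mock arrays. It was above background on 1 of 4 mock arrays, so its folds from mock are uncertain. Hba-a1 was 7.58-fold lower (log2 -2.92 ± 0.51, adjusted p = 0.00591), Rsad2 4.26-fold (log2 -2.09 ± 0.45, adjusted p = 0.0248) and the heat shock gene Hspa1a at least 2.56-fold (adjusted p = 0.000588). In all, 158 genes passed, 77 higher and 81 lower, 30 of them by at least 1 on the log2 scale, and all 158 had the same sign in all 4 mice. With the mouse as a block 338 passed, 165 higher and 173 lower. The other largest rises were those of H2-Ab1 (3.10-fold), Cd74 (3.00-fold), Spsb1 (2.81-fold), Tpbg (2.44-fold), Timp1 (2.41-fold), the gap junction gene Gja1 (2.13-fold) and Sox21 (2.08-fold). The other largest falls were those of Tnfrsf11b (2.92-fold), Ramp3 (2.91-fold), Gimap7 (2.54-fold), Cmpk2 (2.47-fold), Slc7a3 (2.41-fold), Lmo2 (2.32-fold) and Gpnmb (2.26-fold). Tpbg and Timp1 were above background on 1 and 2 of 4 mock arrays. Tnfrsf11b and Hba-a1 were above background on 2 of 4 isoform B arrays, so these folds are uncertain too.

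NF-kB genes were higher as a list (adjusted p = 0.000343, but adjusted p = 0.185 with an estimated correlation). Of 22 members 3 passed, Map3k8 (log2 0.62 ± 0.11), Nfkbie (log2 0.50 ± 0.08) and Rela (log2 0.35 ± 0.08), and 7 adjusted over the list alone. Nfkbia differed by 0.11 ± 0.12 (adjusted p = 0.823) and Tnfaip3 by -0.04 ± 0.12 (adjusted p = 0.948). Of 27 cytokines Il17f, Ccl9, Tnf (1.95-fold) and Il13 (1.59-fold) were higher and 1 was lower (adjusted p = 1.16e-05, but adjusted p = 0.167 with an estimated correlation). Of these, 7 were higher and 1 lower adjusted over the list alone. Of 13 Regnase-1 and Roquin targets Tnf was higher (list adjusted p = 0.0123, but adjusted p = 0.218 with an estimated correlation), and 3 were higher adjusted over the list alone. Of 20 glycolysis genes Slc2a3 (1.80-fold) was lower (list adjusted p = 0.000483, but adjusted p = 0.111 with an estimated correlation), and 3 were lower adjusted over the list alone. Of 18 heat shock and unfolded protein response genes Hspa1a, Ddit3 (2.07-fold) and Ddit4 (1.67-fold) were lower (list adjusted p = 0.000908, but adjusted p = 0.111 with an estimated correlation), and 5 adjusted over the list alone. Of 24 interferon-stimulated genes Rsad2 was lower and Gbp2 (log2 0.48 ± 0.12) higher, with the list lower (adjusted p = 0.00133, but adjusted p = 0.512 with an estimated correlation), and 8 were lower and 2 higher adjusted over the list alone. Without the mock array of mouse 3 that list call was lost too (adjusted p = 0.145, mean -0.226 instead of -0.494).

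Among lists that did not pass with isoform B, 1 gene rose and 1 fell of 21 immediate early genes, Fosb (1.42-fold) and Jund (1.59-fold), also adjusted over the list alone (adjusted p = 0.577). Rcan1 was 1.95-fold higher of 11 NFAT-calcineurin genes, also adjusted over the list alone (adjusted p = 0.43), and Cd40lg 1.48-fold higher of 24 activation receptors (adjusted p = 0.29, with 3 higher and 1 lower adjusted over the list alone). Tsc22d3 (1.70-fold) and Satb1 (1.48-fold) were lower of 19 quiescence genes (adjusted p = 0.449) and Ptpn6 (1.51-fold) of 18 T cell receptor proximal genes (adjusted p = 0.789), with the same counts adjusted over the list alone. No member passed among 11 MALT1 substrates (adjusted p = 0.354, Relb 0.29 ± 0.10), 14 T helper factors (adjusted p = 0.739, Bcl6 -0.51 ± 0.17) and 14 apoptosis regulators (adjusted p = 0.806, Birc5 0.30 ± 0.12), also adjusted over the list alone. The same held for 19 ribosome biogenesis genes (adjusted p = 0.577, Rrs1 -0.29 ± 0.11), 21 mitosis genes (adjusted p = 0.0974, Rrm2 0.30 ± 0.09) and 11 housekeeping genes (adjusted p = 0.449, Gapdh -0.18 ± 0.08, median 0.00519 and mean -0.0565, which differ in sign). Among 16 CBM complex genes 0 passed (adjusted p = 0.276, Prkcq -0.29 ± 0.08, 1 lower adjusted over the list alone). Among 13 MAPK feedback regulators 0 passed (adjusted p = 0.739, Gadd45a -0.52 ± 0.15, median -0.0332 and mean 0.00243, which differ in sign, 1 lower adjusted over the list alone). Among 15 cytokine signalling and STAT genes 0 passed (adjusted p = 0.267, Stat5a 0.52 ± 0.14 with adjusted p = 0.079, or 0.0462 with the mouse as a block, 3 higher and 2 lower adjusted over the list alone).

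Of the B cell marker list, 2 MHC class II pathway genes passed with isoform B as with isoform A. Cd74 (log2 1.59 ± 0.37, adjusted p = 0.0335) and H2-Ab1 (log2 1.63 ± 0.33, adjusted p = 0.0171) were higher of 7 markers, and 4 were higher adjusted over the list alone (list adjusted p = 7.75e-05, but adjusted p = 0.111 with an estimated correlation). The SD of Cd74 was 1.045 over the isoform B arrays and 0.2291 over the mock arrays. Of 4 erythroid and granulocyte markers Hba-a1 was lower, and 2 adjusted over the list alone. None of 9 CD8 and cytotoxic markers (adjusted p = 0.3, Ctsw 0.49 ± 0.17 with adjusted p = 0.203, or 0.00149 with the mouse as a block) or of 4 macrophage and dendritic cell markers (Siglech not above background on any isoform B array) passed, also adjusted over the list alone. With median scaling 64 genes passed, 19 higher and 45 lower, beside the 77 and 81 above, and 61 passed with the isoform B and mock arrays alone. Leaving out the isoform B array of mouse 4 or the mock arrays of mice 3 or 4 left 104, 91 and 88 genes, and 8 genes passed in mice 1 and 2 alone and 19 in mice 3 and 4 alone.

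The differences of both isoforms from mock had the same sign in 72.3% of 8480 genes, where unchanged groups sharing the mock arrays gave 66.6% (65.2% to 67.6% in 100 simulations). Higher with both were 51 genes and lower with both were 58 genes, and 0 genes were called in opposite directions, with the same mock arrays in both comparisons. Across 8480 genes, which are not independent replicates, the log2 differences of isoform A and isoform B from mock correlated with r = 0.711. Such unchanged groups gave 0.502 (0.472 to 0.536 in 100 simulations). The simulation drew genes independently, so its ranges can be too narrow. In the measured data, with the mock arrays split so that the isoforms shared none, r had a mean of 0.406 (0.312 to 0.461). That is not a value for unchanged groups, and it rests on fewer mock arrays per isoform. The covariance of the isoform A and isoform B differences, with all mock arrays shared, was 0.041 against 0.0123 in the simulation, a difference of 0.0287. The 221 genes called higher with isoform A than mock had a median difference of 0.578 with isoform A and of 0.322 with isoform B, and the 77 called higher with isoform B had 0.573 with isoform A and 0.59 with isoform B. The 191 called lower with isoform A had -0.564 and -0.352, and the 81 called lower with isoform B had -0.627 and -0.693, in the same order. Each set was chosen on 1 of the 2 differences, which favours that isoform.

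The last comparison tested the isoforms against each other, which is also the test of whether their differences from mock differ. The amount of each isoform in the cells is not known here. A difference between these groups therefore cannot be assigned to the kind of isoform alone. The chemokine gene Ccl9 was 4.23-fold higher with isoform A than with isoform B (log2 2.08 ± 0.29, n = 4, adjusted p = 0.004) and Il23a 3.54-fold (log2 1.82 ± 0.22, adjusted p = 0.00282). The NF-kB list genes Cd83 (1.92-fold, log2 0.94 ± 0.16, adjusted p = 0.0162), Icam1 (1.76-fold, log2 0.82 ± 0.15, adjusted p = 0.0253), Traf1 (log2 0.57 ± 0.11, adjusted p = 0.04) and Nfkbie (log2 0.51 ± 0.08, adjusted p = 0.00775) were higher too. The signal transducer gene Stat5a was also higher (1.90-fold, log2 0.93 ± 0.14, adjusted p = 0.00775). In all, 18 genes passed, 16 higher with isoform A and 2 lower. The lower genes were Bmi1 (log2 -0.79 ± 0.15, adjusted p = 0.0452) and Card10 (log2 -0.56 ± 0.11, adjusted p = 0.0452). The other largest rises were those of Phldb1 (2.38-fold), Zbtb46 (2.29-fold), Cdk5r1 (2.28-fold), Il1a (at least 1.55-fold) and the chemokine gene Cxcl2 (1.97-fold).

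The NF-kB list was higher with isoform A than with isoform B (adjusted p = 1.64e-11, and adjusted p = 0.0379 with an estimated correlation), with 4 of 22 members higher, or 10 adjusted over the list alone. The list of MALT1 substrates, which shares Tnfaip3, Cyld and Relb with the NF-kB list, was higher (adjusted p = 0.000587, but adjusted p = 0.0701 with an estimated correlation) with no member past the test, 1 adjusted over the list alone, and Tnfaip3 at 0.45 ± 0.12 (adjusted p = 0.198). The mitosis list was lower (adjusted p = 0.0136, but adjusted p = 0.458 with an estimated correlation), again with no member past the test, 1 lower adjusted over the list alone, and Ccne2 at -0.62 ± 0.17 (adjusted p = 0.197). Ccl9 was the 1 cytokine of 27 that passed (list adjusted p = 0.13, 2 higher adjusted over the list alone) and Stat5a the 1 member of 15 in the STAT list (list adjusted p = 0.13, also adjusted over the list alone). No member passed among 21 immediate early genes (adjusted p = 0.327, Nr4a2 -0.90 ± 0.22, 3 lower adjusted over the list alone) or 24 activation receptors (adjusted p = 0.542, Icos -0.56 ± 0.15, 1 lower adjusted over the list alone). None passed among 13 Regnase-1 and Roquin targets (adjusted p = 0.427, 1 lower adjusted over the list alone) or 20 glycolysis genes (adjusted p = 0.31, Slc16a3 0.45 ± 0.10, 1 higher adjusted over the list alone). None passed among 14 apoptosis regulators (adjusted p = 0.705, median -0.0168 and mean 0.0649, which differ in sign, Bcl2l1 0.63 ± 0.17 with adjusted p = 0.194, or 0.0264 with the mouse as a block, 3 higher adjusted over the list alone). The other lists had 0 members past the test, also adjusted over the list alone. These were NFAT-calcineurin genes (adjusted p = 0.13, Nfatc3 -0.67 ± 0.29), CBM complex genes (adjusted p = 0.705, median -0.00717 and mean 0.0112, which differ in sign, Ube2n 0.24 ± 0.11) and T cell receptor proximal genes (adjusted p = 0.13, Ptprc -0.54 ± 0.19). Others were MAPK feedback regulators (adjusted p = 0.83, median -0.00708 and mean 0.0375, which differ in sign, Gadd45a 0.40 ± 0.15), quiescence genes (adjusted p = 0.13, Lef1 -0.58 ± 0.18) and T helper factors (adjusted p = 0.705, median -0.00896 and mean 0.0325, which differ in sign, Irf4 0.37 ± 0.15). Further were ribosome biogenesis genes (adjusted p = 0.13, Ncl 0.33 ± 0.11), interferon-stimulated genes (adjusted p = 0.705, Oas3 0.52 ± 0.30), heat shock genes (adjusted p = 0.243, Hsp90aa1 0.40 ± 0.22) and housekeeping genes (adjusted p = 0.258, Actb -0.39 ± 0.14). Last were B cell markers (adjusted p = 0.243, Fcer2a -0.22 ± 0.13), cytotoxic markers (adjusted p = 0.31, Klrd1 -0.32 ± 0.21), macrophage markers (Ctss 0.18 ± 0.15) and erythroid markers (Hba-a1 0.60 ± 0.51). Nfkbia differed by 0.15 ± 0.12 (adjusted p = 0.771). The calls between the isoforms were fragile: with limma on the isoform A and isoform B arrays alone 0 genes passed, with or without the mouse as a block. In the model of all arrays 815 genes had an unadjusted p under 0.05, and 46 passed there with the mouse as a block. With median scaling 11 genes passed, 1 gene passed in mice 1 and 2 and 75 in mice 3 and 4. Leaving out the mouse 3 array of isoform A or the mouse 2, 3 or 4 array of isoform B left 10, 9, 8 and 9 genes.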

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

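All values in this part were picked out by a fixed rule, and none was followed by a further test. In a group of 4 arrays, 1 array was called far from the others when its gap to the nearest, divided by the range of the group, was above 0.829. Chance alone does this in about 1 in 20 groups, and 22 of 456 groups were picked out where 22.8 were expected, so the list is no longer than chance gives. The far arrays came from mouse 1 in 8 cases, mouse 2 in 3, mouse 3 in 5 and mouse 4 in 6.

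With isoform A stimulated, far arrays were found for Rel (0.995, mouse 4 at 10.1 against 9.8 to 9.81), Dusp4 (0.947, mouse 1), Tbxa2r (0.926, mouse 2), Ddit4 (0.918, mouse 1), Tsc22d3 (0.887, mouse 4), Ikbkg (0.88, mouse 4), Ramp3 (0.864, mouse 3) and Cdc6 (0.837, mouse 3). With isoform A unstimulated they were found for Tbxa2r (0.833, mouse 3) and Igtp (0.829 after rounding, mouse 1). With isoform B they were found for Cdk5r1 (0.947, mouse 2), Jund (0.923, mouse 3), Card10 (0.915, mouse 2), Cd83 (0.909, mouse 4 at 8.53 against 8.26 to 8.29), Ctss (0.891, mouse 1) and Rrs1 (0.844, mouse 4). With mock they were found for Gbp2 (0.956, mouse 1), Map3k14 (0.879, mouse 4), Tpbg (0.865, mouse 1), Cd28 (0.855, mouse 3) and Cd40lg (0.83, mouse 1). The raw median intensity of the mock array of mouse 1 was 138.8 where the other mock arrays had 126.2 to 128.3 (0.833).

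Detected probes that carry no gene name here stood outside the gene comparisons and held signal too. Of 740 such probes, 489 passed the threshold on stimulation, 33 between isoform A and mock, 13 between isoform B and mock and 1 between the isoforms.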

How the results depend on the processing

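The alternatives with mice 1 and 2 or mice 3 and 4 alone, and the interferon list without the mock array of mouse 3 (given in the report), were chosen after the data were seen. Stimulation called 5077 genes or more in each setting without a fold threshold except detection on all arrays (4595, fewer genes tested), and 4610 of the 5634 were shared with median scaling. Genes called were, in the order isoform A against mock, isoform B against mock and isoform A against B (412, 158 and 18 above), 136, 64 and 11 with median scaling, 745, 338 and 46 with the mouse as a fixed block and 678, 319 and 48 with it as a random one. They were 161, 61 and 0 with the 2 groups alone, 185 and 0 (first and last) with these and a block, and 41, 8 and 1 in mice 1 and 2, all with fewer samples. In mice 3 and 4, 19 genes passed for isoform B against mock and 75 between isoforms (29 higher, 46 lower). Without background correction 32 passed between isoforms. A log2 difference of at least 1 left 2533 on stimulation, then 46, 30 and 6. The correlation of the isoforms' differences was 0.406 with the mock arrays split. Of 28 list calls 10 held with an estimated correlation. In the main test 11 lists were called on stimulation, 7 for isoform A against mock, 7 for isoform B against mock and 3 between isoforms. In that order they were 12, 11, 7 and 4 without the detection filter and 20, 11, 5 and 3 in fry. Leaving out a mouse or an array gave 5288 to 5548 genes on stimulation, 133 to 504, 53 to 142 and 0 to 20, and a correlation of 0.657 to 0.721. Single arrays that moved a count by over 1.5 times are named in the report. With the most variable probe Hprt turned to 0.251 on stimulation and Ptprc to 0.171 with isoform A. The apoptosis list on stimulation was not called in the main test (camera, adjusted p = 0.897) and was called lower in fry (adjusted p = 0.00628). Fry lost 5 list calls and added 15 besides that of the apoptosis list. Lost were the interferon list for isoform A (adjusted p = 0.123) and isoform B against mock (0.183) and mitosis genes between the isoforms (0.172). Cytokines and Regnase-1 and Roquin targets were lost for isoform B against mock (0.0554 each). Added for isoform A against mock were, among others, T cell receptor proximal (0.00391), heat shock (0.0102) and housekeeping genes (0.0193), all lower. Beyond the sample and gene numbers, the cause was not tested. Of named genes called, 90 of 94, 31 of 59, 14 of 36 and 0 of 14 kept their call in every alternative fixed beforehand with all samples. The mouse as a fixed block in the model of all arrays changed no other call of a named gene than those given beside the results. A slide block was not run. Malt1 lay near the background, and in the authors' table it gave no value for some comparisons.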

Other observations

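Mock stimulated cells were set against isoform A unstimulated cells, a comparison that differs in both the vector and the stimulus. The genes were chosen on their change with isoform A against the same unstimulated arrays, which favours agreement, and no value without a response was computed. With a change of at least 1, 2530 of 2533 genes had the same sign, at a median of 94.4% of the change with isoform A (quartiles 84.8% and 103%). For isoform B stimulated cells, set against the same isoform A unstimulated cells and so also differing in vector and stimulus, the median was 96.9%. For the 17 NF-kB list genes that rose by at least 1 the median was 80.1% with mock and 90.5% with isoform B, and for the 25 cytokines and chemokines that rose it was 90.4% with mock and 98.7% with isoform B. Across 8480 genes, the difference of isoform B from mock correlated with the stimulation response of isoform A with r = 0.205. The difference of isoform A from mock correlated with that of isoform B stimulated from isoform A unstimulated cells with r = 0.227.

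The tests below on NF-kB response size, on antibody-secreting cells and on splits of the arrays had their predictions written before their values were seen. Those on low intensities, red cells, interferon and B cells were chosen after the result was seen. With the 8 arrays of a comparison split 4 and 4 in all 35 ways, each fitted in the model of all 16 arrays, the real split called the most genes on stimulation (1 of 35 splits as large, 5634 genes, highest other 1), for isoform A against mock (1 of 35, 412 against 49) and for isoform B against mock (1 of 35, 158 against 70). The same splits were fitted on the 8 arrays alone after these values were seen: the real split again called the most genes on stimulation (5626, highest other 0) and for isoform A against mock (161 against 71), but these 35 splits take no account of the mouse. For isoform B against mock 2 of 35 splits reached the 61 genes of the 8 arrays alone, the other being the split of mice 1 and 2 against mice 3 and 4 (101), so whether chance is excluded over 35 splits depends on the model and was left open. Between the isoforms 2 of 35 splits reached the 18 genes, the highest other being 296, and on the 8 arrays alone the real split called 0 genes against 251, so chance could not be excluded there. The highest other split of all 3 comparisons among stimulated cells set mice 1 and 2 against mice 3 and 4, which is a structure of the samples. Among the 8 splits with 1 array of each mouse on each side the highest other count was 0 in all 4 comparisons with either model, but 8 splits are too few to exclude chance at 0.05, so with the mouse kept chance could not be excluded in any comparison by splits alone.

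The NF-kB list was higher by 0.448 (SE 0.075 over 4 mice) with isoform A than with mock, and a weaker response of mock cells over all induced genes could account for 0.0722 of it. The rest was 0.375 (SE 0.062, mice 0.289, 0.401, 0.539 and 0.273). It argues against a weaker response of the size seen outside the lists as the only explanation. Induced genes of the other lists had no part in the prediction, so a weaker response shared with them was not tested. For loss of signal at low intensity the members above the median intensity were taken, which differed by 0.462 (SE 0.082), but these are 20 of the 22 members and nearly restate the list mean, so nothing is drawn from that value. The added isoform is the explanation the design offers, and nothing beyond the groups tests it.

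Hba-a1 was higher with mock in all 4 mice, with isoform A at -0.643, -2.35, -4.3 and -1.98 from it. Red blood cells or their precursors could carry it. Of 5 beta globin probes (for Hbb-bt, Hbb-b2, Hbb-bh1 and Hbb-y) the best was above background on 0 of 4 mock arrays, where Hba-a1 had a mean of 8.18. The erythroid genes Alas2 and Slc4a1 were above background on 0 of 16 arrays (mock means 4.45 and 4.46). These values argue against red cells only if the probes detect their targets and red cells of these mice express those genes. Nothing here shows either. Car2, of the erythroid and granulocyte list, went the way of Hba-a1. It was 1.91-fold lower with isoform A than with mock (limma, adjusted p = 0.0179), so red cells were not excluded. Car2 also rose at least 1.79-fold on stimulation in isoform A cells, so its level need not come from red cells. An interferon response of the same arrays might accompany the level of Hba-a1. Over the 12 stimulated arrays, after group means were removed, Hba-a1 correlated with the mean of the interferon list at r = 0.817 (exact permutation p = 0.039, adjusted 0.078, 13824 arrangements). The r was 0.437 without the 2 arrays farthest from the median and the rank correlation was 0.552 (exact permutation p = 0.128), while r was 0.78 with mouse means also removed. It was 0.96 in mice 1 and 2 and 0.97 in mice 3 and 4. Each of these last 2 values rests on only 1 difference between mice per stimulated group, so little can be drawn from them. The question stays open. The added isoform is the explanation the design offers, and nothing beyond the groups tests it.

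Cd74, H2-Ab1 and Mzb1 were higher with either isoform than with mock, in mice 1 to 4 by 1.31, 2.27, 1.81 and 2.38 for Mzb1 and 1.18, 1.33, 1.76 and 2.32 for Cd74 with isoform A, and by 4.46, 3.1, 2.49 and 1.09 for Mzb1 and 2.91, 1.53, 1.25 and 0.662 for Cd74 with isoform B. B cells left in the cells could give this, and their 3 detected markers had a median difference of 0.0718 (SE 0.059) where Cd74 rose by 1.59. Antibody-secreting cells could too, and their 8 detected markers had a median of 0.0731 (SE 0.021) where Mzb1 rose by 2.78. The prediction written for them called such a value evidence against, but a rule added after the values were seen set it and the like prediction for B cells aside, because all 3 B cell markers and 4 of the 8 others lay near the background and 3 had a high baseline, so under that rule neither source can be told apart from a change within T cells. The cells were sorted CD4-positive T cells per the series design, and an effect of the isoforms on these genes was not tested beyond the groups.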
